A study of Mus musculus with 9 samples.

How the data were processed

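Gene expression was measured by RNA sequencing in mammary tumor organoids of C3(1)-TAg mice, a transgenic line in which a viral T antigen drives mammary tumors. Per the labels' protocols, the organoids were cultured in fibrillar collagen I, assigned to 3 groups by their invasive phenotype, taken out with forceps and lysed for total RNA. The 9 libraries fall into 3 groups of 3, and the labels call the 3 libraries of a group biological replicates from independent experiments. The aligner, the read counter, the genome build and the annotation are not given in the sources used here, and no coordinates are therefore printed.

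The authors deposited 3 tables, 1 for each pair of groups, and each table was normalized separately. Per the file headers, each holds the count of reads per gene summed over the libraries of a group, and the log2 fold change, p-value and adjusted p-value of a DESeq2 comparison, whose version is not given in the sources used here. The deposited z score of each gene equalled the normal quantile of its two-sided p-value with the sign of the fold change. The deposited adjusted p-value equalled the Benjamini-Hochberg adjustment over the 17764, 17325 and 17985 genes that have one in the comparisons of invasive with non-invasive, disseminative with non-invasive and disseminative with invasive organoids. Genes without an adjusted p had at most 31, 41 and 32 reads in those comparisons. A further deposited adjusted p-value equalled the same adjustment over genes with at least 10 reads over the 2 groups. Every gene with reads had a p-value. No table holds values per library. No test across libraries, no SD, no fit with the experiment as a block and no omission of a library was therefore possible, and whether the authors used the experiment as a term in their fit is not given in the sources used here.

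Each table has 60627 lines for 54838 distinct gene IDs, because a mouse gene is repeated for each of its human counterparts, and repeated lines were merged. Symbols came from the GENCODE M21 name table, which held 54723 of the IDs, and otherwise from the tables, which name 20261. Where both named a gene, 99.91% of names were equal, and 64 IDs had no symbol. Reads were found for 27671 genes. Pooled reads in genes came to 120879368 for the non-invasive, 103153674 for the invasive and 120579372 for the disseminative group, so that 1 CPM, scaled to all reads in genes, stood for 120.9, 103.2 and 120.6 pooled reads. Depth per library is not known. The 10 genes with the most reads took between 2.89% and 3.33% of a group's reads.

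A standard error was derived for each gene as its deposited log2 fold change divided by its deposited z. The median ratio of this error to the counting error of the pooled reads was 5.86, 6.26 and 6.67 in the 3 comparisons, so the errors hold spread beyond counting. In genes with over 50 reads in both groups the deposited fold change had a median difference of -0.0028, -0.0287 and -0.0141 (log2) from the ratio of pooled CPM. It lay more than 1 away in 65 of 14319, 102 of 14482 and 111 of 14542 genes. A fold change far from the pooled ratio can arise where the libraries of a group are uneven, and such genes are named as such in the text. Over 13906 genes with over 300 reads, the fold changes of the 3 tables added up with a median residual of -0.0115 (quartiles -0.0121 and -0.011), as unshrunken fold changes from tables with their own size factors do.

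A gene was called changed where the authors' adjusted p was under 0.05. The 38 gene lists were tested with cameraPR of limma 3.58.1 in R 4.3.3 on the authors' z scores, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists of a comparison. This describes the deposited statistics, since a correlation estimated from the libraries needs values per library. A preset of 0.05 was run as an alternative, but it does not replace an estimate, and the correlation within a list may be higher. The p-values of the list tests therefore do not measure spread between libraries. The erythroid list had no tested gene and gave no result. Per list, the members past the threshold were counted over all tested genes and adjusted over the list alone. With members of 3 or fewer reads in a group set to that floor of 3 reads per group, no list's median moved in any comparison. Tables were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and statsmodels 0.14.6, and plots drawn with matplotlib 3.10.9.

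The groups, the gene lists, the threshold and the rule for named genes were set before the data were examined. The rule names 9 fixed genes whatever their result, the 8 largest called fold changes in each direction among genes with at least 5 CPM in the higher group (predicted genes and pseudogenes left out), and up to 4 members with the smallest p from each list past its test. The part of the rule that asked for separated libraries could not be applied without values per library. A test of edgeR on counts per library had been planned and was replaced by the authors' deposited statistics, the alternative planned for tables of this kind.

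The comparisons of invasive and of disseminative organoids with non-invasive ones share the non-invasive libraries. For the values of the correlation, covariance and same-sign share without any effect, 100 sets of chance fold changes were drawn from the derived errors. The variance of the shared group was set to 0.5 of the squared error, averaged over both comparisons. The test of called genes was checked on simulated data, in which 100 genes each were changed by 1 and by 2 (log2) against the real errors. In the comparison of invasive with non-invasive organoids (17752 genes), 54.0% of the genes changed by 1 and 72.0% of those changed by 2 were recovered, with 6 false calls. The values for disseminative against non-invasive (17316 genes) were 47.0%, 67.0% and 4, and for disseminative against invasive (17973 genes) 55.0%, 71.0% and 7. The list test found 4 of 4 changed lists in each comparison and called 1, 0 and 0 of 34 unchanged ones. Genes were drawn independently with normal errors of the derived size, so few false calls follow by construction. The check covers neither the authors' test nor correlation between genes. Its shares of recovered genes need not hold in the data, where the number of changed genes differs.

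Alternatives set before the data were examined and possible here were no filter on low counts, a mean of at least 5 CPM, and a log2 fold change of at least 1. Alternatives added after seeing the data were the deposited adjustment over genes with at least 10 reads, an adjusted p under 0.01, fold changes scaled to total reads or to a median gene of 0, removal of lowess trends on transcript GC content and length (known for at least 99.93% of tested genes), fold changes within 1 of the pooled ratio, and, for the lists, the log2 fold change or ranks in place of z and the higher preset correlation. Scaling moved all fold changes by at most 0.0287 (log2).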

Results

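RNA from mouse mammary tumor organoids grown for 3 days in collagen I was compared between 3 groups defined by phenotype in the gel, namely non-invasive, invasive (collective invasion) and disseminative. Each group held 3 libraries, known only as a pooled total. Reads in genes came to 120879368 for non-invasive, 103153674 for invasive and 120579372 for disseminative organoids. Fold changes are given on the log2 scale with the standard error derived from the authors' z score. Adjusted p-values of genes are those of DESeq2 in the authors' deposited tables, and levels are pooled CPM without a replicate error. The genes named whatever their result were Krt14 (ENSMUSG00000045545), Krt5 (ENSMUSG00000061527), Trp63 (ENSMUSG00000022510), Krt8 (ENSMUSG00000049382), Krt18 (ENSMUSG00000023043), Epcam (ENSMUSG00000045394), Cdh1 (ENSMUSG00000000303), Vim (ENSMUSG00000026728) and Kras (ENSMUSG00000030265). Largest changes are those of called genes with at least 5 CPM in the higher group, predicted genes and pseudogenes left out. The study's title names KRAS-dependent collective and disseminative programs, and the 3 comparisons asked which transcripts set these phenotypes apart.

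Invasive organoids differed from non-invasive ones in the contractile genes of myoepithelial cells, the smooth-muscle-like cells that surround mammary ducts, of which 9 of 14 rose. Acta2, smooth muscle actin, rose by 5.82 ± 0.26 (adjusted p = 2.76e-107) from 11.8 to 452 CPM in the authors' deposited table, and Myh11, smooth muscle myosin heavy chain, rose by 4.86 ± 0.20 (adjusted p = 1.17e-126). Alongside, 9 of 20 basement membrane genes, 12 of 22 fibrillar matrix genes and 9 of 24 matrix proteases and inhibitors rose while 2, 1 and 2 fell, and 5 of 21 hypoxia genes fell. Of 18 fibroblast markers 11 rose, with a median of 3.11 over the list, beside these matrix and protease genes.

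Of 17764 tested genes, 1205 changed between invasive and non-invasive organoids in the authors' deposited table, 749 higher and 456 lower in invasive ones. With a mean of at least 5 CPM, 472 were higher and 403 lower. Of the 1205 genes, 530 higher and 175 lower ones changed by at least 1 on the log2 scale. Among the keratins, Krt5 of basal cells rose by 2.62 ± 0.67 (adjusted p = 0.00283) in the authors' deposited table, and the luminal Krt8 and Krt18 rose by 0.69 ± 0.17 (adjusted p = 0.00258) and 0.67 ± 0.18 (adjusted p = 0.00463). Basal Krt14 stood at 0.31 ± 0.21 (adjusted p = 0.506) and Trp63, the basal lineage transcription factor, at -0.28 ± 0.26 (adjusted p = 0.686) in the authors' deposited table. The epithelial adhesion genes Epcam and Cdh1 stood at -0.30 ± 0.18 (adjusted p = 0.421) and -0.32 ± 0.16 (adjusted p = 0.26) in the authors' deposited table. Vim, the intermediate filament vimentin, rose by 1.42 ± 0.17 (adjusted p = 6.98e-15), whereas Kras stood at 0.39 ± 0.69 (adjusted p = 0.874) in the authors' deposited table.

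Of the 14 tested myoepithelial contractile genes, 9 rose and none fell (10 and 0 adjusted over the list alone), with a median of 3.04 and a list test at adjusted p = 9.67e-60. Myl9 and Actg2, contractile light chain and actin genes, rose by 3.63 ± 0.27 and 4.09 ± 0.30 in the authors' deposited table. Of the 26 genes of EMT (epithelial to mesenchymal transition) factors and mesenchymal proteins, 9 rose and 1 fell (11 and 2 adjusted over the list alone; list test adjusted p = 2.38e-13). They included Tgfb1i1 at 3.53 ± 0.24, Prrx1 at 3.71 ± 0.36 and the matrix glycoprotein Sparc at 1.94 ± 0.20 in the authors' deposited table. In the collagen crosslinking and fibrillar matrix list 12 of 22 genes rose and 1 fell (13 and 2 adjusted over the list alone; list test adjusted p = 7.66e-14). These included the proteoglycan Lum at 3.73 ± 0.33, Fbn1 (fibrillin) at 2.91 ± 0.30, Dcn at 2.88 ± 0.38 and Postn (periostin) at 1.35 ± 0.20 in the authors' deposited table. Of 20 basement membrane genes 9 rose and 2 fell (11 and 3 adjusted over the list alone; list test adjusted p = 3.66e-08). Called members were Nid1 at 3.03 ± 0.29, Col4a1 at 2.39 ± 0.30, Col4a2 at 1.77 ± 0.31 and Lama1 at 5.58 ± 0.72 in the authors' deposited table. Of 24 matrix proteases and inhibitors 9 rose and 2 fell (11 and 2 adjusted over the list alone; list test adjusted p = 7.87e-10). Among them were Mmp10 at 3.23 ± 0.23, the gelatinase Mmp9 at 4.74 ± 0.39, the collagenolytic cathepsin Ctsk at 3.13 ± 0.30 and Mmp3 at 2.13 ± 0.29 in the authors' deposited table.

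ERK pathway output genes included 7 of 22 that rose and none that fell (7 and 1 adjusted over the list alone; list test adjusted p = 7.85e-04). Hmga2 rose by 1.58 ± 0.27, the phosphatase gene Dusp5 by 1.37 ± 0.24, the cyclin gene Ccnd1 by 1.30 ± 0.23 and the ETS factor Etv1 by 2.20 ± 0.52 in the authors' deposited table. Of 30 ribosomal protein genes 14 rose (18 adjusted over the list alone; list test adjusted p = 1.06e-12), by a median of 0.51 over the list, with Rps23 at 0.76 ± 0.20, Rps18 at 0.80 ± 0.21, Rps11 at 0.65 ± 0.17 and Rpl7 at 0.66 ± 0.18 in the authors' deposited table. Ribosomal protein genes have many processed pseudogenes that can share their reads, and Rps11 was no longer called with GC and length trends removed (adjusted p = 0.0955). Hypoxia genes were lower, with 5 of 21 falling and none rising (7 and 0 adjusted over the list alone; list test adjusted p = 6.66e-06). These included Ero1l at -0.87 ± 0.16, Ndrg1 at -0.83 ± 0.18 and Ak4 at -1.18 ± 0.33 in the authors' deposited table. Among 31 G2 and M phase genes only Anln passed, at -0.71 ± 0.16 in the authors' deposited table, and the list test gave adjusted p = 6.21e-04 toward lower values.

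Further lists passed at the preset correlation of 0.01 and not at 0.05. They were luminal epithelial genes (8 of 22 rose; adjusted p = 0.0175 and, at 0.05, 0.0871), inflammatory NF-kB output (3 of 24 rose; 0.00906 and 0.066), p53 targets (1 of 19 rose; 0.0397 and 0.132), oxidative phosphorylation (0 of 24 called; 0.0223 and 0.111) and neutrophil markers (1 of 6 rose; 0.0223 and 0.0648). The lower ones were epithelial junction and identity (2 of 28 fell; adjusted p = 0.0206 and, at 0.05, 0.111), squamous differentiation (3 of 16 fell, 1 rose; 0.0206 and 0.0838), glycolysis (2 of 17 fell; 0.0131 and 0.066) and cholesterol synthesis (1 of 21 fell; 0.0216 and 0.102). Adjusted over the list alone, 9 luminal, 5 NF-kB, 2 squamous, 1 p53 and 1 neutrophil gene were higher. On the same basis 5 squamous, 2 junction, 2 glycolysis, 1 cholesterol and 1 luminal gene were lower, and 0 genes of oxidative phosphorylation were called (6 higher at an unadjusted p under 0.05). The neutrophil call came from Mmp9, also on the protease list, and the median of that list was -0.52 while its test pointed up. Fibroblast markers rose in 11 of 18 cases (12 adjusted over the list alone; list test adjusted p = 3.4e-19). Called members were Col3a1 at 4.18 ± 0.64 and Thy1 at 3.61 ± 0.51 in the authors' deposited table. The lists of basal epithelial, RAS family, actin and migration, TGF-beta, YAP, S phase, apoptosis, interferon, unfolded protein response, immediate early, mitochondrial, macrophage, lymphocyte, endothelial, pericyte, adipocyte, skeletal muscle and Schwann genes did not pass, with adjusted p from 0.0787 to 0.984.

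The largest rises not named above in the authors' deposited table were Apol10b at 6.61 ± 0.75, the teneurin Tenm2 at 6.04 ± 0.74, the surfactant protein gene Sftpd at 9.25 ± 2.73, Lama2 of the basement membrane list at 8.54 ± 2.66, the casein gene Csn1s1 at 6.27 ± 1.72, Col14a1 at 6.23 ± 1.22 and the growth factor Nrg1 at 5.96 ± 1.22. For the last 5 the deposited fold change exceeded the ratio of pooled CPM by 1.83, 5.42, 2.93, 1.18 and 1.42. The largest falls in the authors' deposited table were the hair follicle keratin Krt75 at -3.86 ± 0.81, B3galt5 at -2.81 ± 0.34, the homeobox gene Shox2 at -2.71 ± 0.22, Tmem100 at -2.68 ± 0.55, Odf3l1 at -2.63 ± 0.43, the water channel Aqp1 at -2.42 ± 0.61, Ankk1 at -2.37 ± 0.48 and Pcolce2 at -2.28 ± 0.24. With the log2 fold change in place of z, the ERK, ribosomal protein, hypoxia and G2 and M phase lists no longer passed (adjusted p = 0.429, 0.167, 0.0705 and 0.429). No library could be left out, so the calls rest on the spread as the authors' test measured it.

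Disseminative organoids differed from non-invasive ones by lower junction and basal epithelial lists and higher mesenchymal, matrix, protease and inflammatory lists. The luminal list did not pass (adjusted p = 0.255), but its called genes went both ways, with 5 of 22 lower, Epcam among them, and 3 higher. The adhesion genes Cdh1 (E-cadherin) and Epcam fell by 0.89 ± 0.28 (adjusted p = 0.0214) and 0.86 ± 0.23 (adjusted p = 0.00392) in the authors' deposited table, and the basal factor Trp63 fell by 1.29 ± 0.23 (adjusted p = 2.37e-06). Kras, the RAS family GTPase, rose by 1.91 ± 0.26 (adjusted p = 5.04e-11), from 200 to 876 CPM, in the authors' deposited table, and 10 of the 20 tested genes nearest to it in gene order were called higher too. Of the fibroblast and macrophage markers 9 of 18 and 14 of 19 rose, with list medians of 2.67 and 1.41, beside the matrix, mesenchymal and inflammatory genes.

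Of 17325 tested genes, 1543 changed between disseminative and non-invasive organoids in the authors' deposited table, 973 higher and 570 lower in disseminative ones. Restricting the genes to a mean of at least 5 CPM left 640 higher and 522 lower. Of the 1543 genes, 737 higher and 230 lower ones changed by at least 1 on the log2 scale. Vim rose by 2.33 ± 0.63 (adjusted p = 0.00507) and Krt14 fell by 0.78 ± 0.26 (adjusted p = 0.0395) in the authors' deposited table. The error of Vim was wider than in invasive against non-invasive organoids (0.17), as were those of Fbn1 (1.00 against 0.30) and Dcn (1.11 against 0.38). That of Lum was closer (0.43 against 0.33). Whether the disseminative libraries were uneven in these genes could not be seen without values per library. The Krt14 call did not hold without a filter on low counts (adjusted p = 0.0606) or with scaling to total reads (0.0504). Krt5 stood at -1.16 ± 0.85 (adjusted p = 0.477), Krt8 at 0.12 ± 0.19 (adjusted p = 0.807) and Krt18 at 0.32 ± 0.19 (adjusted p = 0.348) in the authors' deposited table.

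Of 28 epithelial junction and identity genes 7 fell and none rose (11 and 0 adjusted over the list alone; list test adjusted p = 6.04e-08). Among them were the splicing regulator Esrp1 at -0.67 ± 0.19, Ovol1 at -0.90 ± 0.28, the tight junction gene Ocln at -0.87 ± 0.27 and St14 at -0.72 ± 0.22 in the authors' deposited table. Of 25 basal epithelial genes 6 fell and 2 rose (6 and 2 adjusted over the list alone; list test adjusted p = 7.02e-04). These included the desmosomal Dsc3 at -3.82 ± 1.08, Perp at -0.87 ± 0.23 and Lgals7 at -0.82 ± 0.25 in the authors' deposited table. Squamous differentiation genes fell in 3 of 17 cases (4 adjusted over the list alone; list test adjusted p = 0.0253, and 0.0865 at a correlation of 0.05). Called members were Dsg1a at -3.54 ± 0.50, Dsc2 at -1.12 ± 0.26 and Klk10 at -0.70 ± 0.22 in the authors' deposited table. Of 26 EMT and mesenchymal genes 12 rose and 1 fell (15 and 1 adjusted over the list alone; list test adjusted p = 1.74e-08). Among them were the transcription factors Twist1 at 3.77 ± 0.56, Twist2 at 3.59 ± 0.83 and Zeb2 at 1.79 ± 0.35, and Tgfb1i1 at 2.12 ± 0.36, in the authors' deposited table. Contractile genes rose in 5 of 14 cases (7 higher and 1 lower adjusted over the list alone; list test adjusted p = 4.73e-06). These included Acta2 at 2.95 ± 0.35, Tagln at 1.84 ± 0.26, Myh11 at 1.95 ± 0.44 and Myl9 at 1.13 ± 0.30 in the authors' deposited table.

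Fibrillar matrix genes rose in 8 of 22 cases (9 adjusted over the list alone; list test adjusted p = 1.57e-07). Called members were Lum at 5.48 ± 0.43, Dcn at 5.28 ± 1.11, Col3a1 at 6.06 ± 1.43 and Col5a3 at 1.67 ± 0.36 in the authors' deposited table. Basement membrane genes rose in 5 of 20 cases (7 higher and 1 lower adjusted over the list alone; list test adjusted p = 0.00333). Among them were Col18a1 at 1.15 ± 0.23, Nid1 at 3.46 ± 0.83, Lamc1 at 0.91 ± 0.22 and Lamb1 at 0.56 ± 0.16 in the authors' deposited table. Matrix proteases and inhibitors rose in 12 of 24 cases and 1 fell (16 and 1 adjusted over the list alone; list test adjusted p = 1.33e-13). These included Ctsk at 3.84 ± 0.40, Mmp9 at 4.69 ± 0.51, Mmp10 at 2.74 ± 0.38 and the urokinase receptor Plaur at 1.01 ± 0.18 in the authors' deposited table. ERK pathway output genes rose in 7 of 22 cases (9 adjusted over the list alone; list test adjusted p = 2.52e-12). Called members were Hmga2, a chromatin protein, at 2.86 ± 0.17 (adjusted p = 4.16e-59), Ccnd1 at 1.47 ± 0.15 and Etv1 at 3.86 ± 0.54 in the authors' deposited table. In the RAS family and effectors list only Kras rose and only Pik3cb fell among 24 genes (1 and 1 adjusted over the list alone), and the list did not pass (adjusted p = 0.305). Inflammatory NF-kB output genes rose in 10 of 24 cases (11 adjusted over the list alone; list test adjusted p = 2.4e-09). Among them were the cytokine genes Csf3 at 2.84 ± 0.23, Csf1 at 1.02 ± 0.19 and Il6 at 2.86 ± 0.64 and the acute phase gene Saa3 at 3.78 ± 0.79 in the authors' deposited table. Among p53 targets 5 of 19 rose and 1 fell (7 and 1 adjusted over the list alone; list test adjusted p = 3.48e-04). These included Ccng1 at 0.96 ± 0.16, Gadd45a at 1.01 ± 0.21, Mdm2 at 0.85 ± 0.20 and Phlda3 at 0.66 ± 0.20 in the authors' deposited table.

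Mitotic genes were lower, with 3 of 31 G2 and M phase genes falling (6 adjusted over the list alone; list test adjusted p = 1.28e-05). Called members were Cdc20 at -0.65 ± 0.19, Kif2c at -0.63 ± 0.19 and Kif11 at -0.45 ± 0.15 in the authors' deposited table. Hypoxia genes held no call among 21 (0 adjusted over the list alone), 4 lower at an unadjusted p under 0.05, a median of -0.34 and a list test of adjusted p = 0.0076, or 0.0539 at a correlation of 0.05. In the list of immediate early and heat shock genes, a sign of handling stress, 2 of 18 fell (3 adjusted over the list alone; list test adjusted p = 0.0159, and 0.0649 at a correlation of 0.05), the chaperones Hspb1 at -1.17 ± 0.23 and Dnajb1 at -0.63 ± 0.19 in the authors' deposited table.

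Macrophage markers rose in 14 of 19 cases and none fell (17 and 0 adjusted over the list alone; list test adjusted p = 2.38e-20). Among them were Mrc1 at 3.12 ± 0.39, Ctss at 1.19 ± 0.16, the lysozyme gene Lyz2 at 0.96 ± 0.16 and Laptm5 at 1.55 ± 0.26 in the authors' deposited table. Fibroblast markers rose in 9 of 18 cases (13 adjusted over the list alone; list test adjusted p = 3.01e-16). These included Fbln1 at 1.70 ± 0.25, Dpt at 5.42 ± 0.88 and the chemokine Cxcl12 at 3.74 ± 0.66 in the authors' deposited table. Smaller lists of other cell types were higher as well, namely neutrophil (2 of 7 rose; adjusted p = 0.00381), endothelial (2 of 15 rose; adjusted p = 0.018, and 0.0649 at a correlation of 0.05) and adipocyte markers (2 of 4 rose; adjusted p = 0.0337, and 0.0562 at 0.05). Adjusted over the list alone, they held 2, 4 and 3 higher genes and 1 lower endothelial one. The neutrophil calls were Mmp9, also on the protease list, and Mmp8, whose call was lost without a filter on low counts (adjusted p = 0.0627). The lists of luminal epithelial, actin and migration, TGF-beta, YAP, S phase, apoptosis, glycolysis, oxidative phosphorylation, cholesterol, interferon, unfolded protein response, mitochondrial, ribosomal protein, lymphocyte, pericyte, skeletal muscle and Schwann genes did not pass, with adjusted p from 0.066 to 0.969.

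The largest further rises in the authors' deposited table were the adhesion protein gene Svep1 at 6.27 ± 1.13, the chemokine Ccl8 at 6.12 ± 1.22, Lgi2 at 5.87 ± 0.85, Efemp1 at 5.17 ± 0.68 and Col15a1 at 5.04 ± 1.56. The fold changes of Svep1, Ccl8, Col3a1 and Col15a1 exceeded the ratio of pooled CPM by 2.43, 1.31, 1.29 and 1.29. The largest falls besides Dsc3 in the authors' deposited table were Ankk1 at -6.04 ± 1.88, the protease inhibitor Spink5 at -4.68 ± 1.31, Slc46a2 at -4.53 ± 1.26, Krt75 at -4.40 ± 1.24, Dab1 at -3.93 ± 1.20, Htra4 at -3.88 ± 1.33 and the glutamate receptor gene Gria1 at -3.61 ± 0.85. The Htra4 call was lost without a filter on low counts (adjusted p = 0.064), and that of Kif11 with GC and length trends removed (0.108). With the log2 fold change in place of z, the ERK, p53, and G2 and M phase lists no longer passed (adjusted p = 0.0539, 0.615 and 0.2). Nor did the squamous, hypoxia, and immediate early and heat shock lists (0.103, 0.136 and 0.514).

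Disseminative organoids had lower basal and contractile lists than collectively invading ones (12 of 25 and 8 of 14 genes fell) and a higher macrophage list (12 of 19 rose). Basal Krt5 fell by 3.72 ± 0.79 (adjusted p = 4.01e-04) and Krt14 fell by 1.08 ± 0.20 (adjusted p = 2.06e-05) in the authors' deposited table, and Trp63 fell by 1.00 ± 0.22 (adjusted p = 0.0012). Col17a1, the hemidesmosomal collagen, fell by 2.75 ± 0.21 (adjusted p = 1.77e-33) and Acta2 fell by 2.87 ± 0.19 (adjusted p = 7.59e-50) in the authors' deposited table. Zeb1, a repressor of epithelial genes, rose by 1.63 ± 0.31 (adjusted p = 4.2e-05) in the authors' deposited table, in an EMT list of which 4 of 26 rose and 2 fell. That list passed at adjusted p = 0.0217 and did not at a correlation of 0.05 (adjusted p = 0.118).

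Fewer genes were called here than in the other comparisons, 351 of 17985 tested in the authors' deposited table, with 220 higher and 131 lower in disseminative organoids. Of the 220 higher genes, 166 were also called higher in disseminative than in non-invasive organoids. Of the 131 lower genes, 69 were called higher in invasive than in non-invasive organoids and 27 lower in disseminative than in non-invasive ones. These counts share libraries between comparisons and are therefore not independent. Krt8 at -0.55 ± 0.20 (adjusted p = 0.173), Krt18 at -0.34 ± 0.19 (adjusted p = 0.644), Epcam at -0.56 ± 0.20 (adjusted p = 0.164) and Cdh1 at -0.56 ± 0.23 (adjusted p = 0.316) did not pass in the authors' deposited table. Vim stood at 0.94 ± 0.74 (adjusted p = 0.91) and Kras at 1.51 ± 0.75 (adjusted p = 0.526) in the authors' deposited table, with pooled Kras levels of 315 CPM in invasive and 876 CPM in disseminative organoids.

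Of 25 basal epithelial genes 12 fell and none rose (17 and 0 adjusted over the list alone; list test adjusted p = 2.74e-38). Called members were the cadherin Cdh3 at -2.42 ± 0.31, Dsc3 at -3.00 ± 0.36 and Krt6a at -1.96 ± 0.25 in the authors' deposited table. Krt6a has a near copy, Krt6b, and whether reads were shared between them was not tested. Of 14 contractile genes 8 fell (10 adjusted over the list alone; list test adjusted p = 1.3e-56). Among them were Myl9 at -2.49 ± 0.24, Actg2 at -2.87 ± 0.29 and Tagln at -2.26 ± 0.23 in the authors' deposited table. Luminal genes fell in 3 of 22 cases (9 lower and 2 higher adjusted over the list alone; list test adjusted p = 2.68e-08). These included Krt19 at -1.32 ± 0.22, Aldh1a3 at -0.98 ± 0.20 and the progesterone receptor gene Pgr at -3.03 ± 0.80 in the authors' deposited table. Epithelial junction genes held no call among 28 (0 adjusted over the list alone), 9 lower at an unadjusted p under 0.05, a median of -0.37 and a list test of adjusted p = 2.97e-08. Of 30 ribosomal protein genes none was called (0 adjusted over the list alone), while 11 were lower at an unadjusted p under 0.05, with a median of -0.375 and a list test of adjusted p = 5.36e-12.

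Macrophage markers rose in 12 of 19 cases and none fell (16 and 0 adjusted over the list alone; list test adjusted p = 1.13e-32). Called members were Fcer1g at 1.91 ± 0.32, Lyz2 at 1.20 ± 0.22, Mpeg1 at 1.27 ± 0.23 and Ctss at 1.36 ± 0.28 in the authors' deposited table. ERK pathway output genes rose in 2 of 22 cases (3 adjusted over the list alone; list test adjusted p = 5.97e-04). They were Hmga2 at 1.29 ± 0.26 and Etv1 at 1.67 ± 0.44 in the authors' deposited table. EMT and mesenchymal genes rose in 4 of 26 cases and 2 fell (7 and 2 adjusted over the list alone; list test adjusted p = 0.0217, and 0.118 at a correlation of 0.05). Among them were Twist1 at 1.88 ± 0.39, Zeb2 at 1.34 ± 0.33 and Fn1 (fibronectin) at 0.87 ± 0.24 in the authors' deposited table. Fibroblast markers held no call among 19 (0 adjusted over the list alone), 6 higher at an unadjusted p under 0.05, a median of 0.67 and a list test of adjusted p = 0.0252, or 0.111 at a correlation of 0.05. Matrix proteases (2 of 25 rose; 0.00996 and, at 0.05, 0.0785), fibrillar matrix (0 of 22 called; 0.0291 and 0.125), NF-kB output (2 of 24 rose; 0.0166 and 0.103), neutrophil (1 of 9 rose; 0.0345 and 0.103), endothelial (0 of 16 called; 0.0118 and 0.0643) and adipocyte markers (1 of 4 rose; 0.0131 and 0.0267) passed toward higher values, and interferon genes (0 of 26 called; 0.0345 and 0.161) toward lower ones. Adjusted over the list alone, they held 2 protease, 1 higher and 2 lower matrix, 2 NF-kB, 2 neutrophil, 0 endothelial, 2 adipocyte and 0 interferon genes. At an unadjusted p under 0.05, 5 matrix and 6 endothelial genes were higher, 2 matrix genes lower and 0 interferon genes either way. The lists of squamous, RAS family, basement membrane, actin and migration, TGF-beta, YAP, S phase, G2 and M phase, p53, apoptosis, hypoxia, glycolysis, oxidative phosphorylation, cholesterol, unfolded protein response, immediate early, mitochondrial, lymphocyte, pericyte, skeletal muscle and Schwann genes did not pass, with adjusted p from 0.0659 to 0.925.

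The largest rises in the authors' deposited table were Ccn3 at 3.26 ± 0.54, Efemp1 at 2.52 ± 0.67, the WNT deacylase gene Notum at 2.35 ± 0.35, the cytokine Il33 at 2.23 ± 0.42, the sodium pump subunit Atp1a3 at 2.21 ± 0.50, Clec12a at 2.18 ± 0.59, Otulinl at 2.17 ± 0.50 and the autotaxin gene Enpp2 at 2.10 ± 0.31. The largest falls besides Krt5 and Dsc3 in the authors' deposited table were Trp73 at -4.92 ± 0.78, Lama1 at -4.45 ± 0.66, Tenm2 at -3.59 ± 0.54, Homer2 at -3.56 ± 0.38, Lamc3 at -3.50 ± 0.66 and Irx4 at -3.36 ± 0.72. The falls of Trp73 and Irx4 differed by -1.14 and -1.17 from the ratio of pooled CPM. With the log2 fold change in place of z, the junction, ribosomal protein and ERK lists no longer passed (adjusted p = 0.259, 0.24 and 0.546), nor did the fibroblast, adipocyte and EMT lists (0.137, 0.137 and 0.482). The protease, fibrillar matrix, NF-kB and interferon lists did not pass either (0.546, 0.137, 0.457 and 0.754).

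**Figure D1:**
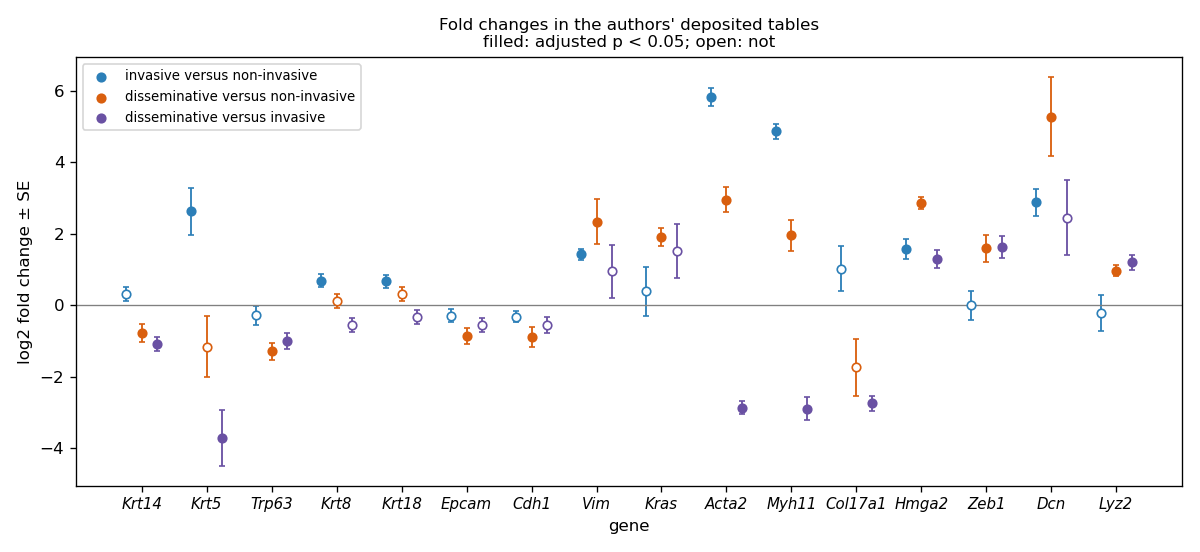
Log2 fold changes (y axis, points, with bars of 1 standard error) of named genes (x axis) in the 3 comparisons of the authors' deposited tables. Filled points have an adjusted p under 0.05 and open points do not, and Acta2 stands at 5.82 for invasive and 2.95 for disseminative against non-invasive organoids.

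**Figure D2:**
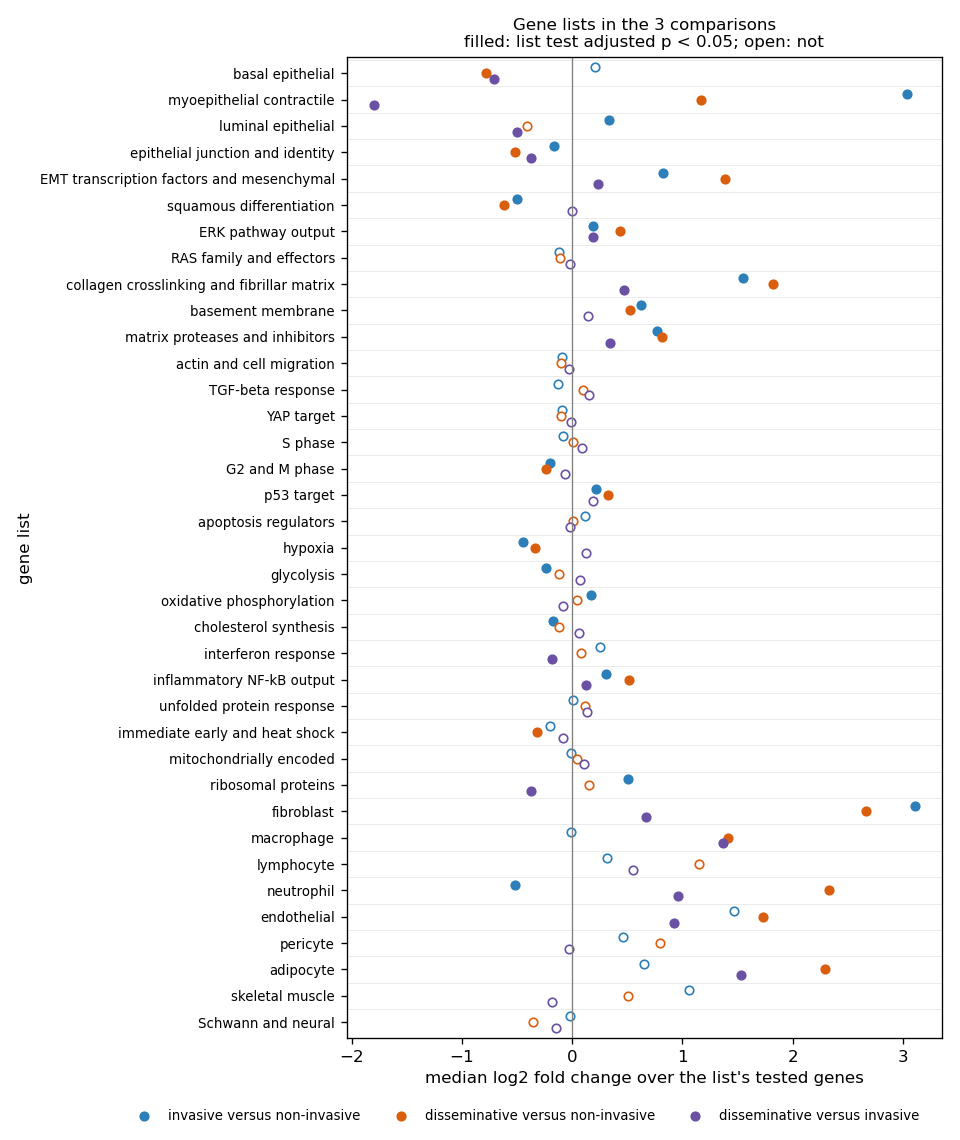
Median log2 fold change (x axis) over the tested genes of each gene list (y axis) in the 3 comparisons, with filled points where the list test passed and open points where it did not. The contractile list stands at 3.04, 1.17 and -1.80, and the macrophage list at -0.01, 1.41 and 1.37, for invasive against non-invasive, disseminative against non-invasive and disseminative against invasive organoids.

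Invasive and disseminative organoids were set against the same non-invasive libraries, and the genes called in both comparisons were counted. Among the 16971 genes tested in both, 359 were higher in both of the 711 and 954 called higher, where independent lists would share 40.0, and 252 were lower in both of the 456 and 570 called lower, where independent lists would share 15.3. No gene was called higher in invasive and lower in disseminative organoids, where independent lists would share 23.9. The reverse held for 1 gene, Ackr3, where independent lists would share 25.6. Shared controls alone raise overlap in the same direction and lower it in the opposite one, so independence is not the value without an effect, and the overlaps were not tested. Across these genes, which are not independent replicates, the log2 fold changes correlated at r = 0.683, where shared controls without any effect gave 0.497, and 75.0% had the same sign against 66.9%. The covariance was 0.661 against 0.226 without any effect, a difference of 0.434. The controls could not be split without values per library, and part of the excess may come from the shared controls.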

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

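The tests on the genes around Kras were chosen only after the result was seen, while those on pericytes, fibroblasts, and GC content and length were set before, though how the pericyte test is read was revised after its result was seen. Each group had 3 libraries and the tables used here hold no values per library, so neither a single library apart from its group nor other splits of the libraries were tested.

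Ackr3, a scavenging chemokine receptor gene, stood out because it was called in opposite directions against the non-invasive organoids in the authors' deposited tables, at -0.81 ± 0.25 (adjusted p = 0.019) in invasive and 0.75 ± 0.26 (adjusted p = 0.0433) in disseminative organoids. The direct comparison of disseminative with invasive organoids in the authors' deposited table gave 1.569 (log2; adjusted p = 3.12e-08), but it uses the same libraries and is nearly fixed by the other values, so it is no independent test.

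Contractile genes were higher in invasive than in non-invasive organoids, with a median of 3.035 (log2). Pericytes or vascular smooth muscle cells as a source stay open, and the test could not decide. The 7 pericyte markers that are not on the contractile list had a median of 0.229, under the bound of 1.518 set before by more than the standard error of 1.173. That bound took no account of markers that go both ways (1 called higher, 1 lower, SD 2.48), nor of Mcam, already at 98.2 CPM in the non-invasive group, which would hide a small share of such cells. Myofibroblasts, and a difference within the tumor cells of the phenotypes that the design names, also stay open and were not tested.

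Genes higher in disseminative than in non-invasive organoids included many fibroblast markers, and fibroblasts carried along could account for part of the 973 genes. The median this needs is there, since the fibroblast list had a median of 2.671 (standard error 0.523, 18 genes) against a bound of 0.5. The prediction also asked for Col1a1, Col1a2, Col3a1, Dcn and Lum all to be higher, and of these only Col1a2 was not called higher. High fibroblast markers are also the pattern to be explained, so passing the bound does not tell their source. Macrophage markers were higher as well, with 14 of 19 called and a list median of 1.41. Whether macrophages contributed to the 973 genes was not tested and stays open. The tables argue against a smooth trend with GC content or transcript length as the whole cause, because 98.9% of the 973 genes (962) were still called higher after trends on both were removed. In all, 1036 genes were then called higher and 485 lower, against 973 and 570 before. A mesenchymal change of the tumor cells, a difference between phenotypes that the design names, raises several of the fibroblast genes too and stays open, untested. Fibroblasts and a mesenchymal change stay open as well for the 749 genes higher in invasive than in non-invasive organoids. There the fibroblast list had a median of 3.11, with 11 of 18 genes called higher. Between disseminative and invasive organoids 0 of 19 fibroblast markers were called. The list still had a median of 0.671 there, and its list test passed toward higher values in disseminative organoids (adjusted p = 0.0252). It did not pass at the higher preset correlation (adjusted p = 0.111) or with fold changes in place of z (adjusted p = 0.137). The absence of calls therefore does not show equal levels of these markers in both groups.

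Genes around Kras were higher in disseminative than in non-invasive organoids, and a gain of the chromosome segment could account for this. The 20 tested genes nearest to Kras in gene order had a median of 2.325 (log2), the highest among 16899 such windows, whose 99th percentile was 0.567, and 10 of the 20 were called higher, among them Bcat1 at 3.92 ± 0.29 and Etfrf1 at 2.60 ± 0.28 in the authors' deposited table. The median was 0.624 for invasive against non-invasive (99th percentile 0.386) and 1.313 for disseminative against invasive organoids (0.357), with 2 and 4 of the 20 called higher. Bcat1 was among the called genes of both, at 2.89 ± 0.40 and 1.02 ± 0.28 in the authors' deposited tables. Kras itself was called in neither, at 0.39 ± 0.69 and 1.51 ± 0.75. These errors were wider than the 0.26 of Kras in disseminative against non-invasive organoids. Genes of other cell types that happen to lie near Kras cannot be told apart from a gain of the segment, since only 5 neighbours had at least 20 CPM in the non-invasive group, with a median of 0.518 (standard error 0.541) against -0.054 over 8384 genes of that level. All 5 stood above 0 and 2 of them, Etnk1 and Rassf8, were called higher, where 5.62% of all tested genes were. Cmas, C2cd5 and Bhlhe41, at 0.335 ± 0.253, 0.276 ± 0.208 and 0.518 ± 0.235 in the authors' deposited table, were not called. Copy number was not measured, and a regulated rise of the region, which goes with phenotypes that the design names, stays open and untested.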

How the results depend on the processing

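The stricter adjusted p, scaling, GC and length, pooled ratio, 10-read and list test alternatives were chosen after seeing the data. No paired analysis was possible because no table holds values per library. For the same reason DESeq2 size factors, refits with DESeq2 or voom, pseudocounts, a fit of 6 libraries, omission of each library, fry, an estimated correlation, and principal components were planned and not run. Total counts of changed genes stayed within 1.5 times under both filters, both scalings, removal of GC and length trends and the pooled-ratio limit. With a mean of at least 5 CPM, however, the genes higher than in non-invasive organoids went from 749 to 472 in invasive and from 973 to 640 in disseminative ones, and the lower ones from 456 to 403 and from 570 to 522. A log2 fold change of at least 1 left 705 and 967 genes against non-invasive organoids, and an adjusted p under 0.01 left 721, 846 and 198 (invasive and disseminative against non-invasive, disseminative against invasive), by construction. With the log2 fold change in place of z, 7 and 6 lists passed for invasive against non-invasive and disseminative against invasive organoids, and with a correlation of 0.05, 10 and 8, where the higher correlation by construction widens the test. For disseminative against non-invasive organoids 14 lists passed under each. Among 54 single list calls, 22 were lost with the correlation of 0.05, 28 with the log2 fold change besides 1 that turned direction, 10 with ranks and 1 with no filter, and none with the scalings. With at least 5 CPM, 49 of the calls held and 2 were lost, and the rest had too few members left to be tested. Among the values of named genes, 6 lost their call with no filter, 4 with GC and length trends removed, 2 with at least 10 reads and 1 with scaling to total reads. The neutrophil list turned direction for invasive against non-invasive organoids with the log2 fold change (adjusted p = 0.993). The correlation between both comparisons with non-invasive organoids moved to 0.785 in genes of at least 5 CPM, where shared controls without any effect gave 0.494. The cause of the changes with the log2 fold change and with the CPM filter was not tested. Depth per library is not known, and genes with few pooled reads had wide errors.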

Other observations

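The genes in this part were chosen after their values were seen. Pooled CPM of the macrophage markers summed to 738.6 in non-invasive, 747.4 in invasive and 1498.9 in disseminative organoids, and those of the fibroblast markers to 337.1, 716.2 and 1183.4. Single genes weigh heavily in these sums. Lyz2 alone stood at 392, 405 and 783 CPM among the macrophage markers, and Gsn at 206, 169 and 217 CPM among the fibroblast markers. None of the 20 macrophage markers is on another list, whereas 6 of the 20 fibroblast markers are, and the 12 tested fibroblast markers on no other list had a median of 2.381 in disseminative against non-invasive organoids.

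Some further genes of adhesion, keratins and macrophages passed the threshold. Itga6, a laminin receptor subunit, rose by 0.75 ± 0.17 (adjusted p = 6.55e-04) in invasive and by 0.75 ± 0.23 (adjusted p = 0.0162) in disseminative against non-invasive organoids in the authors' deposited tables. Krt17, a keratin of basal cells, fell by 0.98 ± 0.17 in disseminative against invasive organoids in the authors' deposited table. Csf1r, the receptor of the macrophage growth factor, fell by 0.99 ± 0.29 (adjusted p = 0.0142) in invasive against non-invasive organoids in the authors' deposited table.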
